A study of Homo sapiens with 12 samples.

How the data were processed

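Gene expression was measured in BJAB, a human B-lymphoma cell line, and in CEM, a human T-cell acute lymphoblastic leukaemia line. Each line carried either an empty lentiviral vector (pLVX) or the same vector with the WNT7A open reading frame. WNT7A is a secreted signalling protein of the WNT family. Per the labels' protocols and the series' design text, Cy3-labelled cDNA was hybridised in 1 colour to NimbleGen human expression arrays with 3 probes for most transcripts and read on an MS200 scanner. The software that extracted the signals, the background correction, the normalisation and the genome build are not given in the sources used here.

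The deposited values are intensities on a linear scale, as the file headers' probe brightness column gives them. Each of the 4 array files holds 140096 spots, of which 5000 are random-sequence control probes and 135096 are probes of 45033 transcripts, called targets below. All but 2 targets have 3 probes. The sorted intensities of the 4 deposited files differed by at most 0.312%, so the authors' values had already been brought to a shared distribution over the 4 arrays, control probes included. The deposited intensities ran from 56.7 to 62733, with a median of 5803 and a 75th percentile of 36382, which is within 1.72-fold of the highest value. Differences between bright targets are therefore compressed, and saturation could not be seen.

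The labels list 12 samples in 4 groups, 3 labelled replicates each. The deposited value table was compared with the array files. In every group its 3 columns held, within 0.005, the intensities of the 3 probes of each target on 1 array. The exceptions were 3 cells per group, all in the 2 targets with fewer than 3 probes. The labelled replicates are thus different probes read on 1 array, and each group was counted as 1 array (n = 1), 4 arrays in all. Values given as "SD over probes" describe the disagreement between a target's probes and are not an error between cultures.

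Background was corrected with normexp (offset 50) on all spots, the control probes were then left out, and the arrays were normalised by quantiles between arrays. A target's level is the mean of the log2 values of its probes. A target was called detected on an array when at least 2 probes exceeded the 95th percentile of that array's random control probes. Where the dimmer array did not detect a target, the difference is given as "at least N-fold", against the lowest target probe signal above that percentile on the dim array or the target's own level, whichever was higher. Quantile normalisation assumes that the arrays share 1 distribution, which was already so in the deposited values.

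Gene symbols came from the RefSeq gene list of GRCh38.p14, matched on transcript accessions without versions. It named 18866 of the 45033 targets (41.9%), 17185 genes. Targets without a match are counted but not named. The build of the array is not given, so no coordinates are printed. For each gene the target with the highest mean signal was used. No gene named here had another target past the size rule in the opposite direction.

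With 1 array per group there is no test within a cell line. Targets were counted by a rule of size: a log2 difference of at least 1 either way, every probe at least 0.5 the same way, at least 2 probes, and detection on the higher array. The effect of WNT7A over both lines and the difference between the lines were fitted with limma (lmFit and eBayes) on the 4 arrays, with cell line and vector as terms, which leaves 1 residual degree of freedom and a prior worth 1.15. Adjusted p-values are Benjamini-Hochberg values over 36562 targets detected on at least 1 array, with a threshold of 0.05. For CEM against BJAB a log2 difference of at least 1 was also required. Nothing says that the 2 arrays of a line came from separate cultures of equal handling, so these p-values measure the spread between these arrays only. That spread is the difference of the WNT7A effect between the lines, so disagreement between the lines counts as error in both comparisons.

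Fixed before the data were examined were the design, the processing alternatives, 27 gene lists, and the rule for the genes named. Of each list, the median log2 difference was placed among 10000 random lists of the same size matched on mean expression, which describes these arrays and is not a test between cultures. A list was called beyond the random range below the 2.5th or above the 97.5th percentile. Of lists of unrelated genes, 1.35 of 27 would lie there in each line by chance. Members of a real list can move together and some genes sit in several lists. The 1.35 is therefore no measure of chance for these lists. Lists were also tested over the 4 arrays with camera, once with a preset correlation of 0.01 and once with an estimated correlation. The rule names WNT7A; per line the 10 genes with the largest difference each way past the size rule; those past it in both lines, at most 10 each way in the same direction and 5 each way in opposite directions; over both lines the 10 each way with the smallest p; for CEM against BJAB the 10 called genes with the largest difference each way; and up to 4 members of each list per comparison. Loci with only a provisional name were passed over, and 2 genes that the rule takes are not reported here.

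On simulated data with the spread of the BJAB arrays (45033 targets, 100 changed at each of 2 sizes), the size rule recovered 95 of 100 targets changed by 1.5 and 100 of 100 changed by 2.5 on the log2 scale, with 169 false calls. That spread came from the BJAB WNT7A minus empty vector differences. The wider CEM spread was not simulated, so no number of false calls is known for CEM. With 4 simulated arrays (36562 targets), limma estimated the WNT7A effect at a median of 1.52 and 2.53 for changes of 1.5 and 2.5 but called 0 of 100 in each set after adjustment. With so few targets changed, the fit thus could not call even changes of that size. Between the lines, where many targets differed, the same fit called 2050. A list of 24 targets shifted by 0.3 reached the 100th percentile of matched random lists; unshifted it lay at 9.13.

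Alternatives were no background correction, negative-control background correction (nec, offset 16), cyclic loess, median scaling, median polish, no filter on dim targets, the deposited value table, leaving out each labelled replicate, which here is a probe, a size of 1.5, no rule on probes, an intensity trend in eBayes, and the 3 columns taken as separate samples. R 4.3.3, limma 3.58.1 and the R package data.table (version 1.17.8) were used, with Python 3.11.15 and matplotlib 3.10.9 for plots. The number of arrays limits the precision of every value.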

Results

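Transcript levels were measured on 4 arrays: BJAB with empty vector, BJAB with WNT7A, CEM with empty vector and CEM with WNT7A, 1 array each. Detected targets numbered 32524 (72.2%) on the BJAB empty vector array, 34010 (75.5%) on the BJAB WNT7A array, 33054 (73.4%) on the CEM empty vector array and 28714 (63.8%) on the CEM WNT7A array. The 95th percentile of the random control probes was 711, 551 and 643 intensity units on the first 3 arrays and 1461 on the CEM WNT7A array. On that array 13.3% of the random probes exceeded the 95th percentile of the CEM empty vector array, against 5.78% and 3.94% on the BJAB arrays. Target levels on the WNT7A and empty vector arrays correlated across targets at r = 0.994 in BJAB and 0.956 in CEM, and those of the empty vector arrays of the 2 lines at 0.846. Targets are not independent replicates.

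The first comparison checks the transgene. WNT7A signal was high on both WNT7A arrays and near background on both empty vector arrays at 2 of its 3 probes. In BJAB the probe at transcript position 367 went from 178 to 51689 intensity units, at least 72.7-fold, and the probe at 501 from 241 to 52325, at least 73.6-fold. In CEM the same probes went from 323 to 12322, at least 19.2-fold, and from 201 to 9769, at least 15.2-fold. The probe at 1512, nearest the 3' end, was above the random controls on all 4 arrays. It read 1499 and 1032 in BJAB, a ratio of 0.688, and 1129 and 4324 in CEM, a ratio of 3.83. Of similarly bright CEM probes, 12.3% were higher by at least that much. As the mean of 3 probes, the target was at least 20.04-fold higher in BJAB (SD over probes 4.96 on the log2 scale) and at least 12.8-fold higher in CEM (SD over probes 2.06). It passed the size rule in CEM but not in BJAB, where its probes disagreed.

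**Figure D1:**
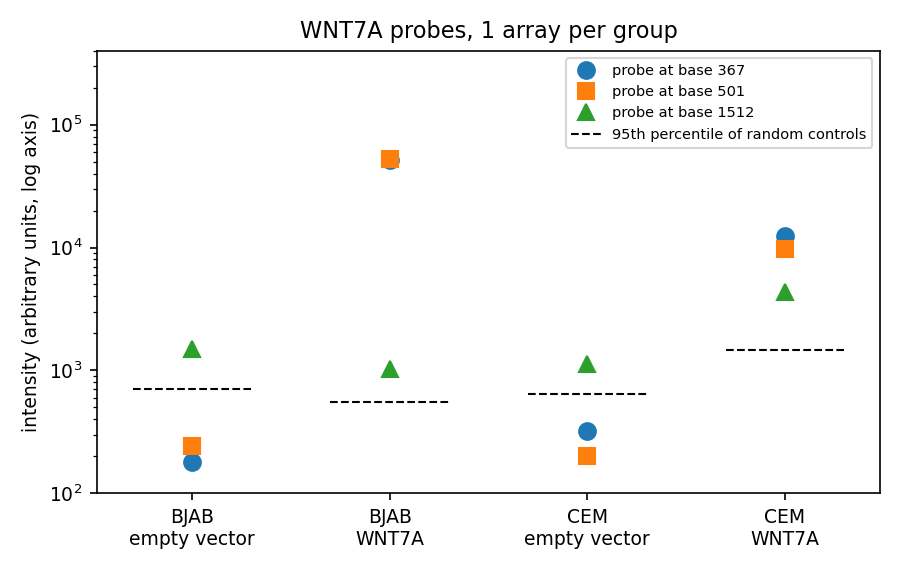
Intensity (log axis) of the 3 WNT7A probes on the 4 arrays, with the 95th percentile of each array's random control probes as a dashed line. The probes at positions 367 and 501 lie below the line on both empty vector arrays and at 9769 or more on both WNT7A arrays, while the probe at 1512 reads 1032 on the BJAB WNT7A array.

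The second comparison asks what differed between BJAB with WNT7A and BJAB with empty vector. The genes with the largest higher signal were INHBE, a subunit of the activin hormones, at a log2 difference of 2.53 (SD over probes 0.14), ADGRG3, an adhesion G protein-coupled receptor, at 2.34 (SD 0.31), CCM2L at 1.88 (SD 0.33) and ATF3, a stress-induced transcription factor, at 1.86 (SD 0.07). SPX and ANTXR2 were each at least 3.06-fold higher, GPR50 at least 1.88-fold, SPMIP9 at least 1.35-fold, NHERF4 at least 1.31-fold and SNCB at least 1.29-fold. Lower with WNT7A were EGFR, the epidermal growth factor receptor, at -2.06 (SD 0.14), COL2A1, a fibrillar collagen chain, at -1.90 (SD 0.40), AFF2 at -1.505, PIP at -1.42, POU2AF2 at -1.40, HEPACAM2 at -1.39, ADGRD1 at -1.34 and HTR3A at -1.31. GASK1B was at least 1.86-fold and FGD5 at least 1.61-fold lower, but FGD5 did not pass the rule with nec (-0.886).

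By the size rule 452 of 34196 targets differed in BJAB (1.32%), 341 higher and 111 lower with WNT7A. There is no replicate array and so no test. On simulated data with the spread of these arrays the rule made 169 false calls, so part of the 452 could arise from spread alone. The median absolute deviation of all log2 differences was 0.188. Of the 341 higher targets, 138 were not detected on the empty vector array, and 224 were either measured on both arrays or at least 2-fold higher by their bound. The stricter size of 1.5 left 76 targets.

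Of the 27 gene lists, 7 had a median above the random range in BJAB and 0 below it. The replication-dependent histone genes had a median of 0.303 (random range -0.05 to 0.07), with 21 of 24 members above 0 and 0 past the size rule. Among the members were H2AC11 at 0.92, H3C8 at 0.68 and H3C10 at 0.60. The correlation between members that camera estimated was 0.68, on 1 residual degree of freedom, so the 24 genes are not separate observations. Whether probes of different histone genes share signal was not tested. The list median was 0.193 with median polish and 0.195 without the third probe of each target. The interferon response genes had a median of 0.205, with 31 of 35 above 0. Of these, CXCL10, an interferon-induced chemokine, was at least 3.55-fold higher and past the size rule, and IFI6 and IFI35 stood at 0.87 and 0.71. The adhesion and migration list had a median of 0.148, with 3 of 44 members past the rule: CCR4, a chemokine receptor, at least 1.85-fold higher, MMP9, a matrix protease, at 1.38, and SELPLG, a selectin ligand, at 1.07. The unfolded protein response list had a median of 0.076, with ATF3 (1.86) and DDIT3 (1.21), both stress-induced transcription factors, past the rule. Smaller shifts were those of the mitosis genes (0.049), the glycolysis and hypoxia genes (0.041, with NDRG1 at 1.23 and PFKFB4 at 1.09) and the reference genes (0.023), which mark how small a shift the random range separates. With undetected members at their bound, the medians were 0.131 for interferon response, 0.057 for the unfolded protein response, 0.047 for adhesion and migration and 0.036 for glycolysis and hypoxia. The adhesion list lay within the random range with nec, and the reference list with cyclic loess and without the first probe.

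The WNT target genes had a BJAB median of -0.042, at the 9.62 percentile of random lists. Of 31 measured members JUN, a subunit of the AP-1 transcription factor, passed the rule, at least 2.70-fold higher. CDX1 stood at -0.69. The WNT receptors and signalling components had a median of 0.046, with ROR2, a WNT receptor, at 1.08 and PORCN, the acyltransferase that modifies WNT proteins, at 1.05 past the rule, and FZD2 at 0.82. The non-canonical WNT list had a median of 0.028, with NFATC4 at 1.35. The WNT ligands had a median of -0.113, where no member passed. That includes the transgene WNT7A, whose probes disagreed in BJAB as given above. The remaining lists lay within the random range: DNA replication (0.005), p53 targets (0.037), CDK inhibitors and G1 regulators (0.035, with CDKN1B, the inhibitor p27, at 1.19), apoptosis regulators (0.043), heat shock genes (0.011), immediate early genes (0.039, with ATF3 and JUN past the rule), cytoplasmic ribosomal proteins (-0.003), cholesterol synthesis (0.029), MAPK feedback genes (0.023) and NF-kB targets (0.069, with 3 of 24 higher, among them EBI3 at 1.25 and CCL22 at 1.02). Markers of T cells (0.010, with RAG1 at least 1.59-fold higher), B cells (-0.024, with FCRL5 at 1.33), monocytes (0.067), epithelial and kidney cells (0.074, with 1 of 19 lower), fibroblasts (-0.115) and erythroid cells and megakaryocytes (-0.062) also lay within it. Of the 10 alternatives, the sign of the median turned under 3 for the T cell and the non-canonical WNT lists, 2 for the monocyte and the epithelial lists, and 1 for the B cell, fibroblast, MAPK feedback and ribosomal protein lists. The WNT receptors lay above the random range with median polish, the WNT ligands below it without the second probe and the fibroblast markers below it without the third. With undetected members at their bound, the median was 0 for the WNT target, ligand, receptor and non-canonical lists and for the T cell, monocyte, epithelial, fibroblast and erythroid markers, and 0.021 for the NF-kB targets. Undetected members without a bound were set to 0 there. Of the WNT ligands, for example, 12 of 19 were not detected on the dimmer BJAB array.

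The third comparison sets CEM with WNT7A against CEM with empty vector. The 10 named genes with the largest lower signal with WNT7A were not detected on the WNT7A array. CD48, a lymphocyte surface protein, was at least 28.9-fold lower, DSG2, a desmosomal cadherin, at least 19.6-fold, RAPGEF4, an exchange factor for RAP proteins, at least 8.17-fold, AHNAK at least 7.13-fold, PTPRK at least 6.75-fold and PRKCA, protein kinase C alpha, at least 5.95-fold. SLC16A14 was at least 6.63-fold, CD109 at least 5.37-fold, RGS9 at least 4.58-fold and PHACTR2 at least 4.51-fold lower. Higher with WNT7A, beside WNT7A itself, were PMP22, a myelin protein, at a log2 difference of 3.53 (SD over probes 0.17), IL12RB1, an interleukin receptor subunit, at 3.01 (SD 0.09), ADGRE1 at 2.92, TNFRSF8, the receptor CD30, at 2.81 (SD 0.16), BCAM at 2.75 and EHD2 at 2.69. The keratin genes KRT73 (3.17) and KRT71 (at least 8.36-fold) and the keratin-associated KRTAP20-1 (2.82) belong to families of similar sequence, so their probes are uncertain.

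By the size rule 5383 of 33509 targets differed in CEM (16.1%), 1863 higher and 3520 lower with WNT7A, and the median absolute deviation of all differences was 0.494. The CEM WNT7A array had the raised random control signal given above. Detection was asked on the higher array, at 1461 units for higher targets and 643 for lower ones. The filter therefore asked more of higher targets, and without it the counts of higher and lower targets lay closer together. Of the 3520 lower targets, 1960 (55.7%) were not detected on the CEM WNT7A array, and 2232 were measured on both arrays or at least 2-fold lower by their bound. There is again no replicate array and no test, and a size of 1.5 left 3300 targets. With detection at the 99th percentile of the random probes, 1049 targets were higher and 2903 lower.

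In CEM 9 lists had medians beyond the random range, 2 above and 7 below, against 6 lists with cyclic loess, 5 without the third probe of each target and 12 without the first. Of the 9, the cholesterol synthesis, histone, mitosis and ribosomal protein lists stayed beyond it on the same side under all 10 alternatives. As given for BJAB, the histone genes are not separate observations. The cholesterol synthesis genes had a median of 0.716 (random range -0.05 to 0.10), the 100th percentile, with 23 of 24 members above 0, 7 past the size rule upward and 0 downward. Among them were CYP51A1 and MSMO1, enzymes of the sterol pathway, at 1.52 and 1.43, and HMGCS1, which makes HMG-CoA, at 1.46. In BJAB the same list had a median of 0.029. The MAPK feedback genes had a median of 0.328, with 2 of 16 higher and 3 lower: ETV5 (1.86) and SPRY1 (1.72) were higher, and SPRY2 (-1.92) and PHLDA1 (at least 1.97-fold) were among the lower. This median was 0.052 with cyclic loess, 0.105 with median polish and -0.137 without the third probe, so its direction is not settled. Beside these lists stands the raised random control signal of the array.

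**Figure D2:**
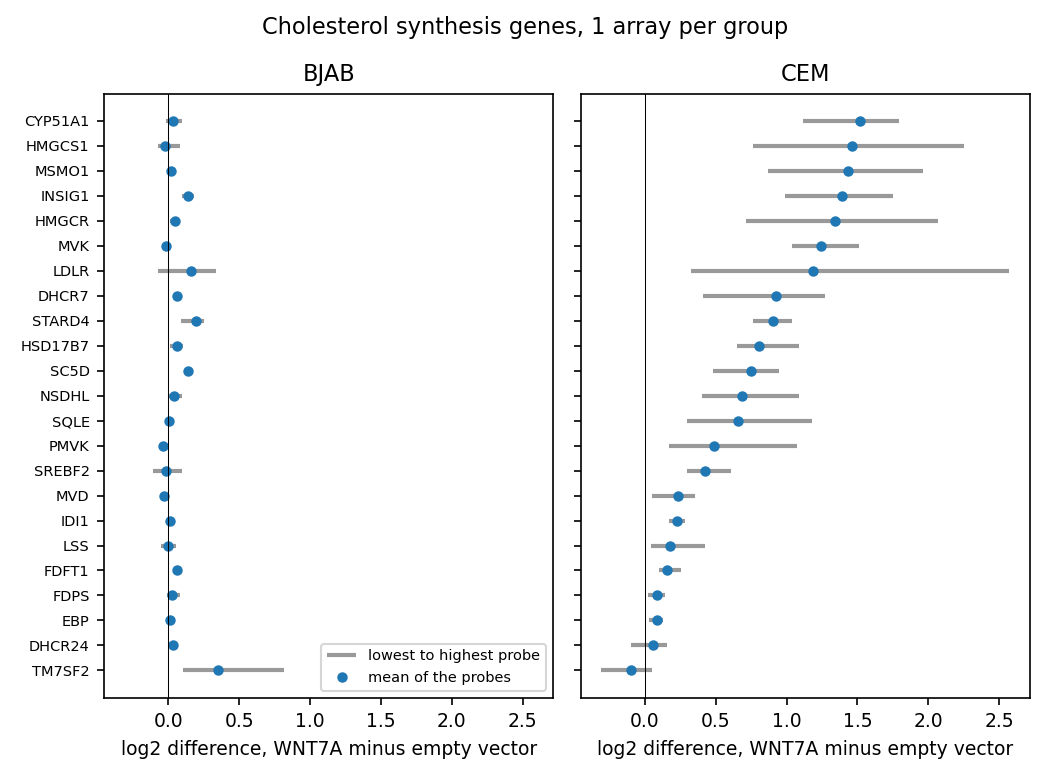
Log2 difference between the WNT7A and empty vector arrays for the 23 cholesterol synthesis genes detected on all 4 arrays, in BJAB and CEM; points are the mean of the probes and lines run from the lowest to the highest probe. In CEM 22 of 23 points lie above 0; the median of the whole list of 24 was 0.716, against 0.029 in BJAB.

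Below the random range in CEM were the replication-dependent histones (median -0.334, 0 of 24 above 0, with H2BC21 at -1.63, H1-2 at -1.06 and H4C5 at -1.05 past the rule), the immediate early genes (-0.236, with JUN at -1.92, FOSB at least 2.60-fold lower and NR4A2 at least 1.07-fold lower), and the WNT receptors and signalling components (-0.126, with 1 of 45 higher and 7 lower by the rule). Of the last, LRP5, a WNT co-receptor, stood at -2.81, KREMEN2 at -2.81 and ADGRA2 at -2.26. The unfolded protein response list had a median of -0.080 (ERN1 at -2.48, DNAJC3 at -1.498), the glycolysis and hypoxia list -0.039 (but SLC2A3 at 1.78 and ANKRD37 at 1.38), the mitosis genes -0.037 and the cytoplasmic ribosomal proteins -0.028. With undetected members at their bound, the medians were 0 for the immediate early genes and the WNT receptors, -0.066 for the unfolded protein response and -0.025 for glycolysis and hypoxia. The immediate early median was -0.016 with nec and -0.014 without the first probe. Of the 10 alternatives, the immediate early genes stayed beyond the random range under 6, the WNT receptors, the MAPK feedback and the glycolysis and hypoxia genes under 7 each, and the unfolded protein response under 8. Without the third probe all of these but the WNT receptors lay within it.

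The WNT target genes in CEM had a median of 0.162, at the 90.5 percentile, with 2 members higher and 5 lower by the rule. AXIN2, a feedback inhibitor of WNT signalling, stood at -1.95 and JUN at -1.92, and RNF43 was at least 2.91-fold lower. The sign of this median turned under 1 of the 10 alternatives, and it was 0 with undetected members at their bound. The WNT ligands had a median of -0.191, with 2 of 19 higher, of which 1 is the transgene WNT7A, and 4 lower, among the latter WNT10A at least 8.93-fold and WNT10B at least 5.22-fold lower. The non-canonical WNT list had a median of -1.3e-04, which changed sign under 5 alternatives, with CELSR2 at -1.32 and NFATC4 at least 2.45-fold lower. Within the random range were also DNA replication (-0.008), p53 targets (-0.051, 3 higher and 4 lower of 29, with BBC3 at least 3.37-fold lower), CDK inhibitors and G1 regulators (-0.101, 3 of 19 lower, with CDKN1B at -2.88), and apoptosis regulators (-0.016, 3 of 34 lower). So were interferon response (-0.091, 1 higher and 7 lower of 35, with MX1 at -2.29), adhesion and migration (-0.008, 4 higher and 6 lower of 44, with CXCR3 at 2.60), heat shock genes (0.065) and reference genes (-0.005). The NF-kB targets had a median of 0.221 with 3 higher and 5 lower of 24, among the latter TNFAIP2 at -3.80 and RELB at -3.45. Markers of T cells had a median of -0.080 (4 of 34 lower, with CD8A at least 2.78-fold lower), B cells 0.019 (1 higher and 5 lower of 34) and monocytes 0.558 (1 of 17 higher). Those of epithelial and kidney cells stood at -0.035 (3 of 19 lower), fibroblasts at 0.089 (5 of 18 lower), and erythroid cells and megakaryocytes at 0.432 (1 higher and 1 lower of 17). With undetected members at their bound, the medians of the WNT ligand, non-canonical WNT, interferon, adhesion, B cell, monocyte, epithelial, fibroblast and erythroid lists were 0. Those of the NF-kB targets, CDK inhibitors and T cell markers were then 0.055, -0.058 and -0.017. Undetected members without a bound were again set to 0. On the dimmer CEM array, 25 of 34 B cell markers and 17 of 17 monocyte markers were not detected. The sign of the median turned under 6 of the 10 alternatives for the B cell list, 5 for the fibroblast list, 3 for adhesion and migration, and 1 for the WNT ligand, DNA replication, apoptosis, epithelial and reference lists. The NF-kB targets, at the 97.47 percentile, lay above the random range under 6 alternatives, and the CDK inhibitors, at 2.77, below it under 4. The DNA replication, p53, heat shock, monocyte and fibroblast lists left the range under 1 each.

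**Figure D3:**
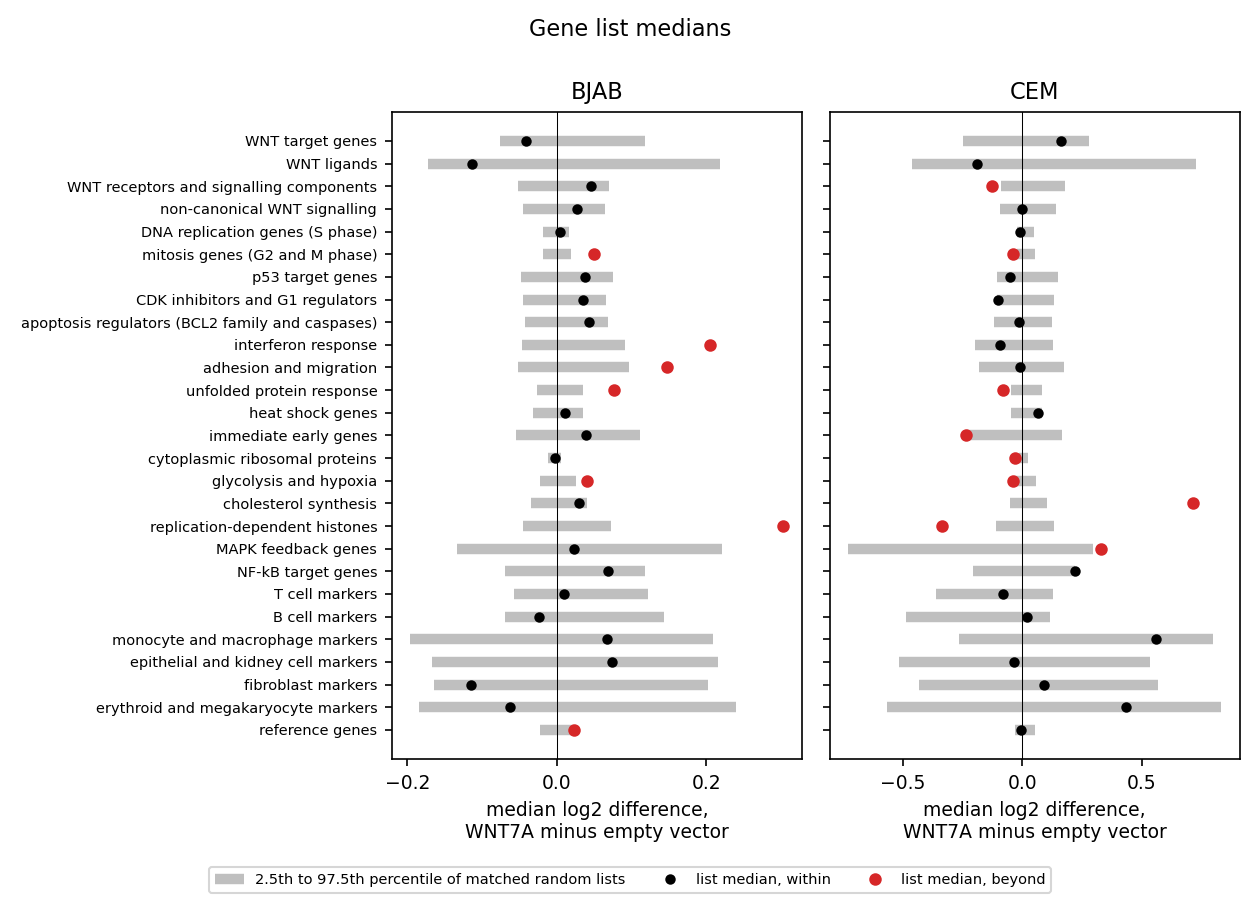
Median log2 difference between the WNT7A and empty vector arrays for 27 gene lists in BJAB and CEM, with the central 95% of expression-matched random lists as grey bars and medians beyond it in red. In BJAB 7 lists lie beyond their bar, all above; in CEM 9 do, with cholesterol synthesis at 0.716.

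The fourth comparison asks whether WNT7A had the same effect in both lines. Across 36562 targets detected on at least 1 array the log2 differences of the lines had a Spearman correlation of -0.141 and a Pearson correlation of -0.117, and on 26863 targets detected on all 4 arrays the Spearman value was -0.200; genes are not independent replicates. Of the targets past the rule, 13 were higher in both lines, against 17.4 expected of independent lists, and 16 lower in both, against 10.7. In opposite directions, 89 were higher in BJAB and lower in CEM, against 32.8 expected, and 3 the other way, against 5.66. These expected numbers ignore brightness. The brightest of 4 classes held 14047 targets, but only 7 of the 341 higher and 0 of the 111 lower in BJAB. In CEM it held 102 of the 1863 higher and 153 of the 3520 lower. Targets past the rule were thus mostly dimmer in both lines, which makes the expected numbers too low. How far the 16 and the 89 exceed chance was not tested. The arrays of each line are separate, so the 2 comparisons share no control, and none of these differences between the lines was tested. Of the genes past the rule in opposite directions, BEST1 stood at 1.62 in BJAB and -2.13 in CEM, RAB38 at -1.20 and 1.32, and JUN was at least 2.70-fold higher in BJAB and at -1.92 in CEM. TNFRSF9 was at least 2.11-fold higher in BJAB and at least 5.18-fold lower in CEM. XKR3 stood at 1.66 in BJAB and was at least 1.40-fold lower in CEM. ARRDC4 was at least 3.75-fold lower in CEM, but in BJAB it had no bound and did not pass the rule with nec (0.91), so an opposite direction is not shown. By the naming rule, CCR4 was higher in both lines, at least 1.85-fold in BJAB and at 1.06 in CEM. MME, the membrane peptidase CD10, was lower at -1.23 and -1.92, NNAT at -1.07 and -1.16, COL2A1 at -1.90 in BJAB and at least 1.64-fold in CEM, and PTCHD1 was at least 1.48-fold lower in BJAB and not detected on the CEM WNT7A array. PTCHD1 did not pass the rule in either line with nec (-0.735 and -0.905). With cyclic loess NNAT did not pass in BJAB (-0.998), nor CCR4 (0.908) and RAB38 (0.961) in CEM.

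**Figure D4:**
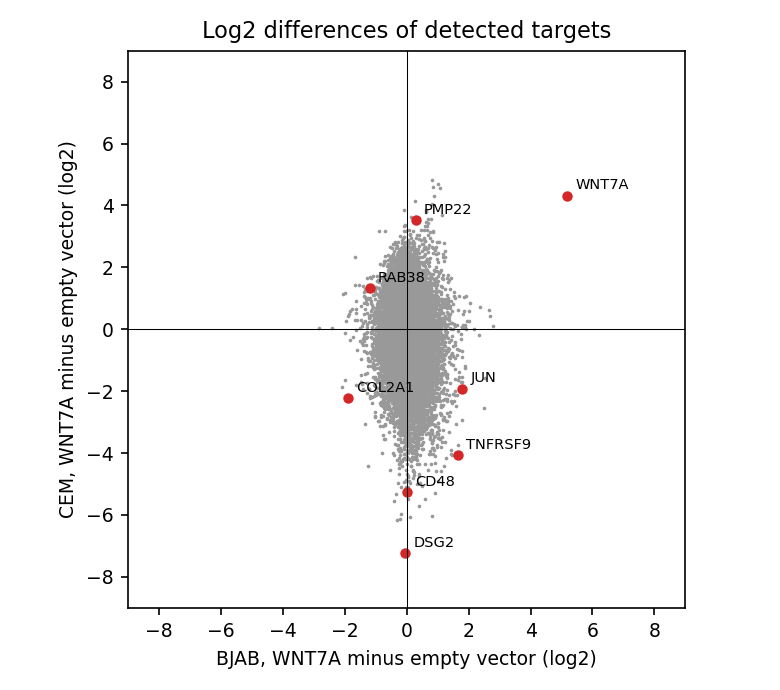
Log2 difference between the WNT7A and empty vector arrays in BJAB (horizontal) and CEM (vertical), 1 grey point per detected target, with 8 named genes in red. The cloud is wider along the CEM axis, and the Spearman correlation across targets is -0.141.

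Fitted over both lines with limma, 0 of 36562 targets passed an adjusted p of 0.05, and the smallest adjusted p was 1.000. At an unadjusted p under 0.05 there were 684 targets, 322 higher and 362 lower, against 1828 expected by chance. The error of this fit is the difference of the effect between the lines. These counts therefore cannot separate a small effect from one that differs between the lines. On simulated arrays of the same design limma called 0 of 100 targets at a log2 change of 2.5. The smallest p was that of WNT7A (limma, log2 difference 4.75, SE 0.32, unadjusted p = 0.00328), higher in both lines. That difference rests on empty vector signals that were not detected, so the bounds above, at least 20.04-fold and 12.8-fold, stand for its size. Within the list of WNT ligands it passed when adjusted over the list alone (limma adjusted p = 0.0426). No other list member passed that way. Both p-values of WNT7A depend on how close the lines stood, at 5.18 in BJAB and 4.32 in CEM over all its probes. Without the probe at 1512, which was not higher in BJAB with WNT7A, they stood further apart, at 8.04 and 5.50. These p-values thus rest in part on that probe and on undetected empty vector signals, and the probe intensities above are the better evidence. After WNT7A the smallest p-values among higher genes were those of LINGO1, EDN2, RIN2, CCL23, PORCN, SCNN1B, TREM1, EPHA4 and TNNT2, and among lower genes those of GSX1, COL2A1, ADAMTS4, NNAT, SLC28A3, SIAE, RYR3, CAPN2, P2RX2 and PLN, none of which passed the adjustment. The probes of GSX1 and TNNT2 disagreed in BJAB, with an SD over probes of 2.88 and 2.67. Median and mean effects over both lines differed in sign for the p53 target, apoptosis, interferon, unfolded protein response and MAPK feedback lists. Of the lists, cholesterol synthesis was called higher by camera with the preset correlation (adjusted p = 1.2e-04), with BJAB and CEM medians of 0.029 and 0.716, and not with the estimated correlation (adjusted p = 0.960). The estimate for this list was 0.83, far above the preset. The estimated form rests on 1 residual degree of freedom and could hardly call any list.

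The last comparison sets CEM against BJAB and checks the lineage labels. Of the T cell markers 19 of 34 were higher in CEM, 0 lower and 15 not called, and 27 of 34 passed when adjusted over the list alone. SH2D1A, a signalling adaptor of T cells, was at least 82.1-fold higher, GATA3, a transcription factor of T cells, at least 79.4-fold, TRAT1 at least 73.8-fold and BCL11B at least 58.6-fold (limma, adjusted p = 0.032 each). Of the B cell markers 21 of 34 were lower in CEM and 0 higher, 29 when adjusted over the list alone. HLA-DRA, an antigen-presenting molecule, was at least 56.9-fold higher in BJAB, MS4A1, the B cell antigen CD20, at least 53.5-fold, FCRLA at least 51.9-fold and EBF1 at least 35.2-fold (limma, adjusted p = 0.032 each). The median log2 difference was 3.82 for T cell and -5.13 for B cell markers, or 3.56 and -4.28 with undetected members at their bound.

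Other genes with the largest differences were ITM2A, at least 89.6-fold higher in CEM, CRY1 at least 80.0-fold, TEX30 at least 79.2-fold, SOX4 at least 74.9-fold, TMEM123 at least 58.0-fold and NDN at least 44.1-fold. Higher in BJAB were HLA-DQA1 at least 56.2-fold, MYBPC1 at least 55.5-fold, CD180 at least 55.1-fold, UCHL1 at least 53.7-fold, BASP1 at least 49.6-fold, PDGFD at least 48.7-fold and IGF2BP1 at least 35.3-fold. In all, limma called 2050 of 36562 targets, 934 higher and 1116 lower in CEM, with a smallest adjusted p of 0.0320, and 10345 targets had an unadjusted p under 0.05. Of the adhesion and migration genes 6 of 44 were higher and 2 lower in CEM (20 adjusted over the list alone), with VIM, an intermediate filament protein, at least 92.0-fold higher. Of the NF-kB targets 3 of 24 were lower, among them CD40, a receptor of B cells, at least 50.2-fold. Of the immediate early genes 4 of 27 were lower, among them DUSP5 at least 28.5-fold. With the preset correlation camera called T cell markers higher and B cell markers lower (adjusted p = 2.6e-15 each), and NF-kB targets (0.00357), immediate early genes (0.00498), monocyte markers (0.0211) and p53 targets (0.0456) lower. With an estimated correlation no list passed (adjusted p = 0.902 for T and B cell markers, 0.967 for the others). That form rests on 1 residual degree of freedom, so it says little about these calls. An intensity trend in the spread raised the count of called targets to 6609, and the empty vector arrays alone gave 10380 targets past the size rule.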

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

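The tests of non-specific hybridisation, of the cultures and of the WNT7A probe, the test of degraded RNA without the rule on probes, and the values of gene families, were chosen only after the results were seen.

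The random control probes of the CEM WNT7A array stood out: 13.3% of them exceeded the 95th percentile of the CEM empty vector array, where 5% do by definition. Differences between the lines follow, none of which was tested, since the interaction has no residual degrees of freedom on 4 arrays. Targets higher in BJAB and lower in CEM numbered 89, and 3 went the other way. The log2 difference in CEM minus that in BJAB was -3.70 for JUN, -5.40 for XKR3, -5.70 for TNFRSF9, -3.75 for BEST1 and -4.65 for ARRDC4, with signal higher in BJAB and lower in CEM, and 2.52 for RAB38, lower in BJAB and higher in CEM. For JUN, XKR3, TNFRSF9 and ARRDC4 these values rest in part on arrays that did not detect the gene. At the bounds the differences were -3.35, -2.15 and -3.45 for the first 3 of them, and ARRDC4 had no bound in BJAB, so its opposite direction is not shown. For lists beyond the random range in opposite directions, the CEM median minus the BJAB median was -0.638 for replication-dependent histones, -0.157 for the unfolded protein response, -0.086 for mitosis genes and -0.079 for glycolysis and hypoxia genes. In CEM the unfolded protein response and the glycolysis and hypoxia lists lay within the random range with median polish and without the third probe. The glycolysis and hypoxia list also lay within it without the second probe.

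In the first pattern weighed, the wider spread of differences in CEM, raised non-specific hybridisation on the CEM WNT7A array stays open as the whole cause of the higher targets. Of these 1863 targets, 45.2% gained more intensity than the 99th percentile of the array's random probes, 4170. So did 26.2% of the higher members past the rule of the keratin, keratin-associated, cornified envelope and olfactory receptor families. Those families were chosen after the data were seen, and whether their gain was specific was not tested, so the test cannot decide. This is the last of 3 forms of the test, whose bounds were all set after values had been seen: the earlier forms, without the families, read 56.3% (level above that percentile, bound 55) and 45.2% (gain, bound 20), and either would have excluded the explanation. For the lower targets, degraded RNA would have spared 3' probes, but the median 3' minus 5' difference was -0.149, or -0.187 for targets taken without the rule on probes, which that rule could otherwise have removed, and -0.021 over all detected targets. Of all 3520 lower targets, however, 55.7% were not detected on the CEM WNT7A array. Background can set both end probes there, so the medians say little about degraded RNA in those targets. A less sensitive array stays open, since the shared distribution holds the median of equally bright targets near 0 whatever the cause (4.58% of that of the lower targets), and WNT7A expression cannot be told apart from other differences between the CEM cultures with 1 array per group, for either part.

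The second pattern is the cholesterol synthesis list in CEM. After cyclic loess, which removes a brightness-dependent shift, its median was 0.707, still at the 100th percentile. The random lists were already matched on mean expression, so this outcome was largely fixed in advance and adds little. Non-specific signal in 1 probe per target is argued against by 91.7% of members (22 of 24) having all probes higher. Non-specific signal shared by all probes of a target was not tested for this list. Whether WNT7A expression or another difference between the transduced cultures, such as density or serum, lies behind it cannot be told apart, with 1 array per group.

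The third pattern is the WNT7A probe nearest the 3' end. A vector transcript that holds the coding sequence without the natural 3' end stays open: the BJAB ratio of 0.688 there, against at least 72.7-fold and 73.6-fold at the other probes, prompted this explanation and does not support it. It does not predict the ratio of 3.83 in CEM, but 12.3% of similarly bright CEM probes were higher by as much, so that value excludes neither this explanation nor a probe that measures nothing. Earlier forms of both tests, without the similarly bright probes, had favoured the first explanation and excluded the second. Where the coding sequence ends relative to this probe was not checked, and no biological explanation was tested.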

How the results depend on the processing

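The alternatives with 99th percentile detection, with the empty vector arrays only and with targets detected on all 4 arrays were chosen after seeing the data. No correlation reversed, nor did any of the 61 gene differences named within a line, and a count cannot reverse. Over 10 alternatives, the median changed sign at least once for 8 of 27 lists in BJAB and 11 in CEM. Of lists beyond the random range only the MAPK feedback genes in CEM did (0.328 to -0.137 without the third probe); the widest others in CEM were the WNT ligands (-0.191 to 0.097), epithelial (-0.035 to 0.140), B cell (0.019 to -0.168) and fibroblast lists (0.089 to -0.996), and the WNT targets went from 0.162 to -0.021. Of lists within the range, 3 of 20 in BJAB and 7 of 18 in CEM left it at least once, the NF-kB targets in CEM under 6 alternatives; the cause was not tested. For the 61 gene results named within a line, 12 alternatives gave 732 values: 709 kept their direction and stayed past the size rule, 23 kept their direction but no longer passed, 12 of them at a size of 1.5. With no filter on dim targets and with no rule on probes the same differences met a looser rule, so all 61 had to pass. A size of 1.5 also kept the differences, so no direction could turn there. Leaving out 1 probe could not turn a direction either, since the size rule had asked every probe to go the same way. The lack of reversals under these settings is therefore no sign of stability. The count of targets over both lines stayed at 0 in every setting run.

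A size of 1.5 gave 76 targets in BJAB and 3300 in CEM, by construction fewer. Cyclic loess gave 1422 higher and 4367 lower targets in CEM, against 1863 and 3520, and the cause was not tested. No filter on dim targets gave 3421 higher and 3899 lower. The filter asks detection on the higher array, at 1461 units for higher targets and 643 for lower ones. It thus removed more of the higher targets. Detection at the 99th percentile gave 322 targets in BJAB and 3952 in CEM (1049 higher, 2903 lower). The correlation between the lines was -0.154 with nec, -0.153 with cyclic loess, -0.131 without the filter and -0.200 on targets detected on all 4 arrays. For CEM against BJAB the intensity trend gave 6609 calls, and the empty vector arrays alone 10380 targets by size with no test. With an estimated correlation camera called 0 lists in both comparisons, from 1 and 6. That form rests on 1 residual degree of freedom. In CEM against BJAB the estimates for T and B cell markers, -0.016 and -0.027, lay below the preset 0.01. A higher correlation therefore did not undo those calls, and the 0 says little about whether they hold. Leaving out 1 probe number at a time, the CEM lists beyond the random range ran from 5 to 12. Without the third it was 5: the unfolded protein response, immediate early, glycolysis and MAPK feedback lists lay within the range; the cause was not tested.

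Taking the 3 columns of a group as separate samples, limma called 102 targets in BJAB and 3441 in CEM without a replicate block, and 1963 and 12458 with the replicate number as a block. These numbers stand for probes, not paired samples, so the block removes differences between probes and its calls describe 1 array per group. Median scaling moves almost nothing on values already brought to 1 distribution, and the value table holds the same intensities as no background correction, so neither says much about stability. Each cell line alone leaves no test. The WNT7A difference ran from 3.64 to 8.04 in BJAB and from 3.64 to 5.50 in CEM without 1 probe, against empty vector signals that were not detected at the probes at 367 and 501, so these are not measured sizes. Signal over background limits the dim targets most on the CEM WNT7A array.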

Other observations

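Gene families chosen after the data were seen showed further shifts. In CEM with WNT7A, 28 of 67 keratin-associated protein genes were higher and 0 lower by the size rule, as were 6 of 27 late cornified envelope and SPRR genes (0 lower), 14 of 53 keratins (1 lower) and 13 of 361 olfactory receptors (1 lower), of which 59 were detected on any array. With undetected members at their bound, the median log2 differences were 0.75, 0.33, 0.34 and 0. Without bounds they were 1.40, 1.40, 1.09 and 0.77, with nec 1.13, 1.05, 0.70 and 0.33, and with cyclic loess 1.08, 1.08, 0.76 and 0.49. Of the members of these 4 families past the rule, 61 were higher and 2 lower in CEM (96.8% higher), against 539 higher and 1381 lower genes in all (28.1% higher). The detection filter was stricter for higher than for lower targets in CEM. In BJAB 0 members of the families were higher and 1 lower. These families are near-identical in parts, and the array had the raised random control signal. Of 26 taste receptor genes, 6 were lower in CEM and 1 in BJAB, and 0 higher. Their CEM median was -0.80, from -0.45 with nec to -1.11 with cyclic loess, and 0 at the bounds. In BJAB it was -0.30, -0.11 with nec and -0.027 at the bounds.

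The correlation of the 2 lines' differences changed with brightness. In 4 classes from dim to bright it was 0.08, -0.10, -0.20 and -0.23, across targets, which are not independent replicates.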
